A study of Danio rerio with 28 samples.

How the data were processed

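The series measured newly made RNA in whole zebrafish embryos over zygotic genome activation, the period in which the embryo's own genome begins to be transcribed and maternal RNA stops being the main source of transcripts. Per the labels' protocols, embryos were injected with s4UTP, a uridine nucleotide with a sulfur atom that is built into new RNA. Labelled RNA was then biotinylated and enriched on magnetic beads. Iodoacetamide (IAA) alkylates the sulfur so that reverse transcription reads a changed base there, which is the chemistry of SLAM-seq. The mutant embryos, mir430-/-, also received miR430 by injection, per the labels. Libraries came from a stranded kit without poly(A) selection, so RNAs without a poly(A) tail were not selected against. The deposited table describes its counts as of the proper orientation, and the strand setting of the counting is not given in the sources used here.

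There were 28 libraries at 4 stages (256c, 1024c, Oblong and Sphere). Wild type and mutant each had 3 IAA libraries per stage, which makes 24 libraries in 8 groups. A further 4 wild type libraries, 1 per stage, had no IAA. The labels call the 3 libraries of a group biological replicates and say nothing of clutches, so p-values measure the spread between these libraries.

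The deposited counts are whole-number counts per gene that the authors made, with no normalization, per the file headers and the values. Their column headings call them filtered, and what was filtered is not given in the sources used here, so it is unknown whether they hold all reads or only reads with converted bases. The table holds 1 count per gene and library, so the planned comparison of read classes could not be run. The table has 32520 genes, each with an identifier, a symbol, coordinates and an exonic length. Per the submitters' processing notes the genome build was GRCz11 and the tools were Trimmomatic, HISAT, SAMtools, Picard, featureCounts and DESeq2, without versions. No genome of that build was used here, and no sequence is given. Of the identifiers, 29201 matched the table of gene names. The authors' deposited table of comparisons gives, per gene and stage, a log2 fold change with its standard error, a p-value and an adjusted p-value, and it flags mir430 and mitochondrial genes. The authors' adjusted p-values and log2 fold changes were used only for comparison with the results below.

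All tests were run on the deposited counts. One edgeR model (version 4.0.16, with limma 3.58.1 and R 4.3.3) held the means of the 8 groups. It used TMM scaling, the filterByExpr filter and a quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The filter kept 14732 genes. Fold changes are from this fit, with the standard error derived from the quasi-F statistic. CPM values are scaled by TMM. The IAA effect was tested over the 16 wild type libraries with stage as a covariate, where 12267 genes passed the filter.

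Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over lists and stages. Lists with fewer than 5 tested genes were not tested, and the pattern for spliceosomal RNAs matched 0 symbols. 1 gene and 1 list that were tested are not reported here. Lists were also run with an estimated correlation and with fry. The genes that rose in wild type from 256c to 1024c were tested the same way at Oblong and Sphere, whose libraries did not define the list, with p adjusted over these 2 stages. Named genes were chosen by a rule fixed before the data were examined. The mir430 genes came first. Then came, per genotype comparison, the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap, with at least 5 CPM in the higher group and a symbol that is not a clone name. For 3 libraries against 3, chance alone separates the groups for 10% of genes. Up to 2 risen and 2 fallen members per list followed, and the wild type steps used 5 in place of 8. A fold against a group with 0 counts is a lower bound computed with 3 counts over that group. With 1 to 3 counts, the ratio is given with its 95% binomial counting interval. Such intervals, and Wilson intervals for single libraries, cover counting error only.

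Depth ranged from 4960211 to 13803137 counts over the IAA libraries, and from 143490 to 1105928 over those without IAA. Over all IAA libraries most counts were mitochondrial, so nuclear depth was far lower. The pairs of replicates differed beyond sampling noise, with a chi-square per degree of freedom between 5.21 and 70.9 over 24 pairs, so no library was counted as a repeat of another.

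The procedure was tested on simulated data drawn from the real means and dispersions, with 14732 genes and 50 genes changed per fold size. Changes were planted only among genes above a minimum mean count at the stage, and genes were drawn independently. Recovery of genes with fewer counts, and false calls from variation shared across genes, were therefore not measured. At 256c, 0% of genes changed 2-fold were recovered, 12% of those changed 4-fold, 56% of those changed 8-fold and 76% of those changed 16-fold. At Sphere these were 0%, 2%, 32% and 74%. Of the calls, 1.37% were false at 256c, 8.06% at 1024c, 3.17% at Oblong and 8.47% at Sphere. The common dispersion of the real data was 0.356, a coefficient of variation of 0.597.

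Replicate numbers were checked for pairing through the correlation of same-numbered libraries' deviations from their group means. All 3 correlations exceeded 0.1 for the genotype comparison at Oblong (0.198, 0.19 and 0.112), for the wild type step from 256c to 1024c (0.278, 0.193 and 0.173) and for the step from Oblong to Sphere (0.78, 0.672 and 0.469). The other comparisons did not pass this check, though the replicate block was fitted over all 8 groups. Differently numbered libraries were not compared, so these correlations do not establish a pairing. The labels do not say what a shared number stands for.

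Alternatives fixed beforehand were DESeq2 (version 1.42.0), total-count scaling, no filter on low counts, at least 5 CPM in 3 libraries, a fit of only the stages compared, the replicate block, each library left out in turn, the library without IAA as a 4th wild type library, removal of mitochondrial genes and genes named as rRNA, and a fold of at least 2. Leaving out all libraries numbered 1, thinning nuclear counts to be equal, and a test of mutant 256c against wild type 1024c were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.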

Results

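Newly made RNA was profiled in wild type zebrafish embryos and in mir430-/- embryos injected with miR430, at 256c, 1024c, Oblong and Sphere. The mir430 locus is a dense cluster of microRNA genes that is transcribed very early. Per the design text, the comparison asks how losing major transcription bodies affects genome activation. Per the labels, the miR430 injected into the mutant embryos was a rescue. The labels name this injection for the mutant embryos only. The deletion, the injected miR430 and the background of the line therefore cannot be told apart in any genotype comparison below. The 24 libraries treated with IAA held 3 replicates per genotype and stage, with between 4960211 and 13803137 counts each.

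Mitochondrial transcripts made up most of the counts of each IAA library except wild type Sphere replicate 3 and mutant Sphere replicate 2. Nuclear genes held 2.15% ± 0.804 of the counts in wild type at 256c, 6.24% ± 1.01 at 1024c, 10.5% ± 3.87 at Oblong and 38.5% ± 24.9 at Sphere (SD, n = 3). In the mutant they held 5.17% ± 2.53, 6.26% ± 2.19, 13.3% ± 2.19 and 45.3% ± 14.9 at the same stages (SD, n = 3). A two-sided exact permutation test between genotypes gave p = 0.3, 1, 0.4 and 1 in stage order, where 0.1 is the smallest p that 3 against 3 allows, so no difference could pass 0.05. At 256c, 15685 ± 1848 nuclear genes had counts in the mutant against 12453 ± 795.4 in wild type (SD, n = 3; exact permutation p = 0.1, the smallest possible). The wild type 256c libraries held between 160889 and 204534 nuclear counts and the mutant ones between 258302 and 634140.

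**Figure D1:**
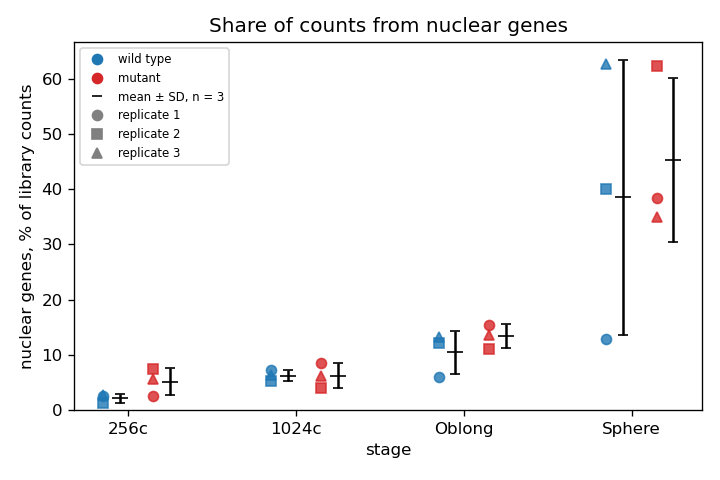
Share of each library's counts that fell on nuclear genes, in percent, by stage, for wild type (blue) and mutant (red), with marker shapes for replicate numbers and black bars for the mean ± SD of 3 libraries. Wild type means went from 2.15% at 256c to 38.5% at Sphere, with a wide spread at Sphere.

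The targeted genes were examined first. The table lists 54 mir430 genes on chromosome 4 between 28693371 and 28709534 (GRCz11), and 1 elsewhere, on chromosome 10. In wild type the chromosome 4 genes took 8.42% ± 5.17 of nuclear counts at 256c, 14.6% ± 11.6 at 1024c, 5.09% ± 3.59 at Oblong and 3.35% ± 1.64 at Sphere (SD, n = 3). In the mutant they took 0.00773% ± 0.0131, 0.00537% ± 0.0068, 0.000774% ± 0.00111 and 0.000108% ± 0.000187 (SD, n = 3). Summed over the 3 libraries, the mutant held 61 counts at 256c against 42970 in wild type, and 9 at Sphere against 320125. At Sphere, 2 mutant libraries had 0 counts, which allows shares of up to 8.04e-05% and 0.00011% of their nuclear counts. Of the 50 mir430 genes tested, 43 fell at 256c, 47 at 1024c, 41 at Oblong and 43 at Sphere. The genes are short copies of one family, which leaves the split of reads among them uncertain.

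**Figure D2:**
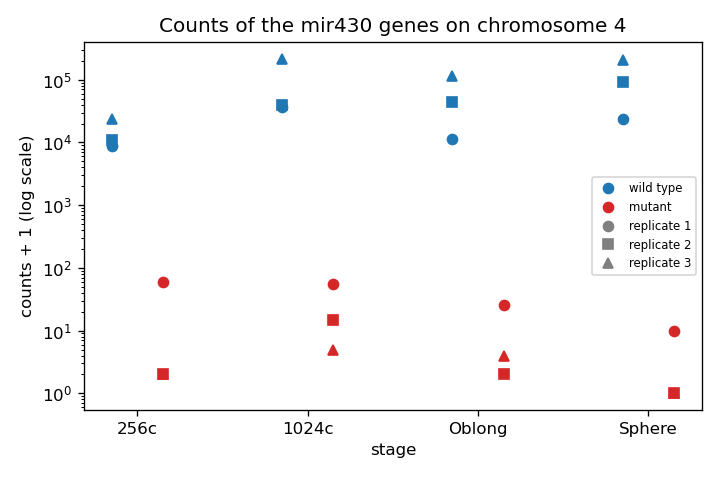
Counts of the 54 mir430 genes on chromosome 4 per library, plus 1, on a log scale, by stage, for wild type (blue) and mutant (red), with marker shapes for replicate numbers. The libraries shown were treated with IAA, and each wild type one held at least 8865 counts and each mutant one at most 59. The mutant libraries numbered 2 and 3 overlap at 256c and at Sphere.

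At 256c, 972 genes were higher in the mutant and 423 lower, 43 of the latter being mir430 genes, among 14732 tested. In the list of early zygotic regulators, 17 of 32 tested members rose, none fell, and 24 rose when adjusted over the list alone. Without wild type 256c replicate 1 or 2 or mutant replicate 3, 4, 8 or 5 of them rose, and 10 did with only the 256c libraries fitted. The GATA factor gene gata2a reached 62.3 ± 58.4 CPM in the mutant against 0.829 ± 0.857 in wild type (SD, n = 3), a log2 fold change of 6.15 (SE 1.14, adjusted p = 0.00176). The zinc finger transcription factor gene zic2b had 11.2 ± 9.51 CPM in the mutant and 0 counts in wild type, at least 38.4-fold higher. Of the signalling list (Nodal, BMP, Wnt and FGF), 7 of 23 members rose and none fell, and 11 rose when adjusted over the list alone. Leaving out any 1 of these 3 libraries left 3. They included bmp2b, a ventralizing ligand, with 27.3 ± 23.2 against 0.693 ± 0.656 CPM (adjusted p = 0.00242), and tdgf1, the Nodal co-receptor, with 56.4 ± 25.9 against 3 ± 0.84 CPM (SD, n = 3; adjusted p = 0.00287). foxh1, the Nodal-responsive transcription factor in the list of maternal activators, had a log2 fold change of 4.96 (SE 0.97, adjusted p = 0.00231), and it was the only called gene of 11.

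**Figure D3:**
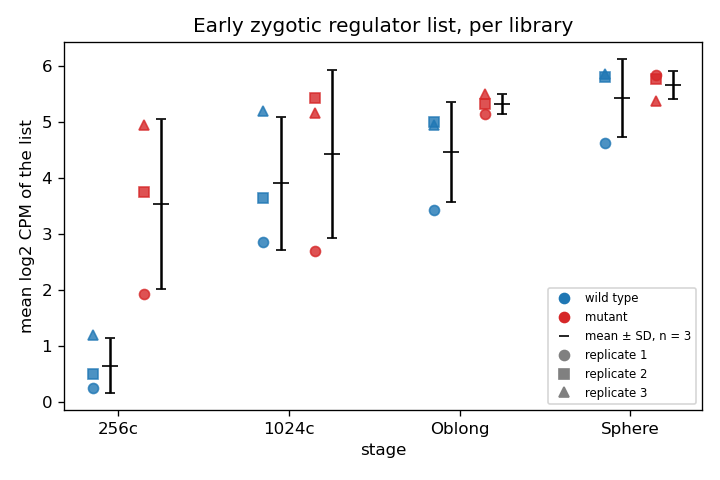
Mean log2 CPM of the 32 tested early zygotic regulators in each library, by stage, for wild type (blue) and mutant (red), with marker shapes for replicate numbers and black bars for the mean ± SD of 3 libraries. At 256c the mean was 0.66 ± 0.49 in wild type and 3.54 ± 1.51 in the mutant, and at Sphere it was 5.43 ± 0.69 and 5.66 ± 0.25. The mutant libraries at 256c stood at 1.93, 3.75 and 4.94, and the highest wild type one at 1.21. A two-sided exact permutation test between genotypes at 256c gave p = 0.1, the smallest that 3 against 3 allows.

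Members of the enveloping layer, cell cycle, histone and znf lists also rose at 256c. Of 13 tested genes of the enveloping layer, the outer epithelium of the early embryo, 6 rose, as they did adjusted over the list alone. The keratin gene krt8 had 15.6 ± 8.11 CPM in the mutant against a single count in wild type, a ratio of 158 with a counting interval of 28.1 to 6260. grhl1, a grainyhead epithelial factor, had a ratio of 85.5 (interval 15.1 to 3400) and an adjusted p of 0.00357. Among 10 yolk syncytial layer genes 2 rose, the homeobox genes mxtx1 and mxtx2, and 5 rose when adjusted over the list alone. gadd45ba, a growth arrest gene, had 65.7 ± 60.3 against 3.13 ± 2.46 CPM (SD, n = 3; adjusted p = 0.00299), while the DNA damage recognition gene ddb2 fell by 3.1 on the log2 scale (adjusted p = 0.0274). In the cell cycle list, 4 of 24 members rose, wee1 among them, and 1, the CDK inhibitor gene cdkn1bb, fell, while 12 rose and 1 fell adjusted over the list alone. Of 54 histone genes 15 rose and none fell, and 20 rose adjusted over the list alone. Of 318 znf genes 61 rose and 4 fell, and 79 rose and 5 fell adjusted over the list alone. Many histone and znf genes are near-identical copies, so their individual counts are uncertain. Without wild type 256c replicate 1, 2 or 3 or mutant replicate 3, 0, 1, 3 or 1 histones, 13, 17, 24 or 14 znf genes and 2, 2, 3 or 3 enveloping layer genes rose, and without mutant replicate 2, 9 histones. Without wild type replicate 1 or 2 or mutant replicate 1 or 3, 2, 2, 8 or 1 cell cycle genes rose, and without wild type replicate 1, 2 or 3 or mutant replicate 3, 1, 0, 0 or 0 yolk syncytial genes.

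Genes of the transcription machinery went both ways at 256c. In the elongation list, 3 of 30 members rose and 2 fell, and 5 rose and 2 fell adjusted over the list alone. cdk9 (chromosome 21, 6136981 to 6150568, GRCz11), the kinase subunit of the elongation factor P-TEFb, had 27 ± 5.83 CPM in the mutant against 5.16 ± 4.48 in wild type (SD, n = 3; log2 fold change 2.36, SE 0.67, adjusted p = 0.0253). brd2a, a bromodomain gene, had a log2 fold change of 3.95 (adjusted p = 0.0116). ctr9, of the PAF complex, fell by 3.11 on the log2 scale (adjusted p = 0.00149) and supt5h, an elongation factor gene, fell by 2.96 (adjusted p = 0.00208). In the Mediator and TFIID list, 2 of 42 rose and 5 fell, and 2 rose and 6 fell adjusted over the list alone. In the microRNA pathway list, 2 of 25 rose, ago3b and dgcr8, and 3 fell, with equal counts over the list alone. ago3b had 20.3 ± 12 CPM in the mutant against 2 counts in wild type, a ratio of 92.1 (interval 25.3 to 764).

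The rises with the largest fitted fold at 256c were in genes with 0 counts in wild type. znf1051 had 54.4 ± 45.4 CPM in the mutant, at least 190-fold higher, and fezf2, a forebrain transcription factor gene, 25.5 ± 28.6 CPM, at least 84.1-fold higher (SD, n = 3). mapk12b was at least 44.4-fold, znf1052 at least 30.7-fold, hadh at least 29.4-fold, the immediate early gene ier2a at least 28.5-fold and srek1ip1 at least 26.3-fold higher. The bounds use 3 counts over the wild type group. Among the falls, btr02 was at least 31.6-fold lower in the mutant. nol4la had a ratio of 96.7 (interval 16.6 to 3890), afmid of 94.8 (interval 16.3 to 3820) and arhgap45b of 59.3 (interval 15.8 to 500), each with 1 or 2 counts in the mutant. ognb, pou6f1, cuedc1b and usf1 also fell, with adjusted p between 0.00071 and 0.00823.

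By camera with the preset correlation, 8 of 20 lists passed at 256c, 7 of them upward. The early zygotic list had a median log2 fold change of 4.25, or 3.3 with genes without wild type counts at their bound, and 31 of its 32 members were positive (camera adjusted p = 4.24e-11). The signalling list (adjusted p = 1.92e-05), the znf genes (1.02e-05), the histones (0.00117), the enveloping layer (0.00462) and the cell cycle list (0.024) also shifted upward. The 13 mitochondrially encoded genes shifted downward, with a median of -0.68 (adjusted p = 0.035, and 0.0891 with total-count scaling) and none called. No list passed with an estimated correlation, where each of these 8 had an adjusted p of 0.989, and none passed with fry's test of a shift in 1 direction. By fry's test of change in either direction, the elongation (adjusted p = 5.25e-06), Mediator and TFIID (1.18e-05), microRNA pathway (8.14e-05), cell cycle (0.00261), early zygotic (0.0363) and enveloping layer (0.0448) lists passed. Total-count scaling moved the median of all genes from 0.24 to 0.96 and gave 1901 genes higher and 185 lower, so 91.1% of calls were upward against 69.7%. Without replicate 1, 2 or 3 of wild type 256c, 318, 377 or 435 genes were higher and 250, 262 or 258 lower; without mutant 256c replicate 2, 243 were lower, and without replicate 3, 384 were higher and 227 lower.

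**Figure D4:**
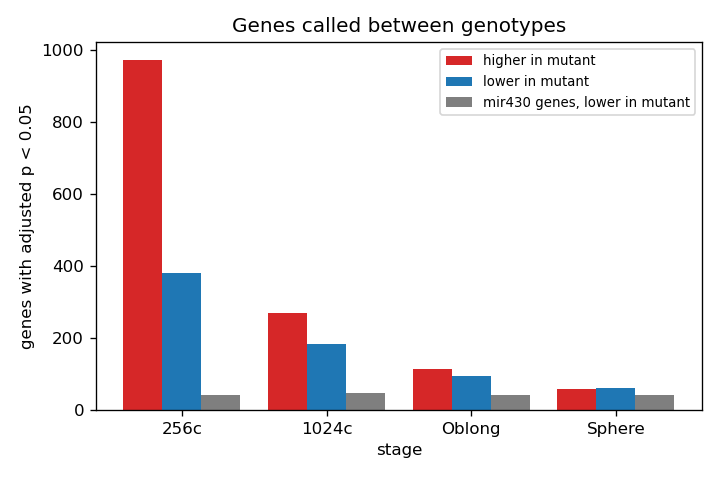
Number of genes with an adjusted p under 0.05 between genotypes at each stage, with bars for genes higher in the mutant, genes lower in the mutant without mir430, and mir430 genes, all of them lower. The bars for higher genes stand at 972, 270, 114 and 58 in stage order.

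At 1024c, 270 genes were higher in the mutant and 230 lower, 47 of the latter being mir430 genes. prdx1, a peroxiredoxin gene, had 36.7 ± 4.94 CPM in the mutant against 0.517 ± 0.16 in wild type (SD, n = 3; log2 fold change 6.11, SE 0.75, adjusted p = 9.93e-05). gbgt1l4 had 24.9 ± 12.9 CPM against 1 count, a ratio of 486 (interval 86.8 to 19200). ap1s3b, an adaptor complex gene, had 13.5 ± 4.7 against 0.211 ± 0.0675 CPM, and mif4gda had a ratio of 88.7 (interval 24.2 to 738). eppk1, prdm8, her12 and foxa2 completed the largest rises, with SDs above their means in the mutant and adjusted p between 0.0145 and 0.0428. Among the falls, cbr1l had a ratio of 111 (interval 19.5 to 4410), ralgapa1 of 42.9 (interval 14.4 to 211) and ttc39c of 36.6 (interval 12.2 to 180). sars1, a seryl-tRNA synthetase gene, had 0.347 ± 0.309 against 9.47 ± 2.88 CPM (SD, n = 3; adjusted p = 0.0018). pimr201, afg1la, cuedc1b and adck2 also fell.

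None of the 32 early zygotic regulators and none of the 23 signalling genes was called at 1024c, and none passed adjusted over the list alone. The early list had a median log2 fold change of 0.57 (camera adjusted p = 0.269). That median depended on single libraries: it was 0.13, 0.3 or 1.66 without wild type 1024c replicate 1, 2 or 3 and 0.93, 0.19 or 0.14 without mutant 1024c replicate 1, 2 or 3, and the list passed without wild type replicate 3 (adjusted p = 0.00153) or mutant replicate 1 (adjusted p = 0.00141). By camera 1 of 20 lists passed, and none passed with an estimated correlation. By fry's test of change in either direction the elongation (adjusted p = 8.14e-05), microRNA pathway (0.00267) and Mediator and TFIID (0.00965) lists passed. In the elongation list ell rose, ctr9 and supt5h fell, and 3 rose and 3 fell adjusted over the list alone. cdk9 had 23.9 ± 16 against 5.9 ± 1.9 CPM (SD, n = 3; adjusted p = 0.0844). In the microRNA pathway list ago3b and dgcr8 rose and cnot3b fell, 3 of 25, and 2 rose and 2 fell adjusted over the list alone. Of 318 znf genes 6 rose and 1 fell, and 3 rose and 0 fell adjusted over the list alone. krt8 rose in the enveloping layer list, 1 of 13, and apoba in the yolk syncytial list, 1 of 10, where 2 rose adjusted over the list alone. Of the histones 1 of 54 rose, h3f3b.1, and in the Mediator and TFIID list taf7 fell, 1 of 42, with equal counts over each list alone. DESeq2 gave 522 higher and 404 lower. Without wild type 1024c replicate 1, 2 or 3, 88, 100 or 156 genes were higher; 115 or 110 were lower without its replicate 1 or 2, and 117, 126 or 109 without mutant replicate 1, 2 or 3. Without wild type 1024c replicate 3, 6 lists passed, and without mutant 1024c replicate 1 or 3, 7 or 2.

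At Oblong, 114 genes were higher in the mutant and 136 lower, 41 of them mir430 genes. With the replicate block 257 were higher and 242 lower. Same-numbered libraries deviated alike at this stage, which does not establish a pairing. slc25a23b, a mitochondrial carrier gene, had 24.8 ± 11.8 against 0.122 ± 0.123 CPM (SD, n = 3; log2 fold change 7.51, SE 1.39, adjusted p = 0.00391). prdx1 had 24.3 ± 5.2 against 0.378 ± 0.14 CPM (adjusted p = 0.000159), gbgt1l4 a ratio of 138 (interval 46.9 to 671) and nyap2b a ratio of 83.6 (interval 22.8 to 695). purba, wscd1b, fgfr1bl and ap1s3b also rose. hmgcrb, which encodes HMG-CoA reductase of sterol synthesis, had 0.241 ± 0.0639 against 8.13 ± 3.46 CPM (SD, n = 3; adjusted p = 0.00318). rrad, a small GTPase gene, had 0.45 ± 0.206 against 13.2 ± 7.09 CPM, and f8, coagulation factor VIII, 0.519 ± 0.0776 against 10.7 ± 8.32 CPM. pimr201, laptm4b, suclg2, sars1 and cdca7b also fell.

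Few members of the fixed lists were called at Oblong. tdrd5, a tudor domain gene of the germ plasm list, fell, as it did at the other 3 stages, with 0.196 ± 0.136 against 1.89 ± 0.181 CPM here (SD, n = 3; adjusted p = 0.02). ago3b and znf1052 rose, and znf385c, with 0 counts in the mutant, was at least 9.24-fold lower. Adjusted over the list alone, 2 genes of the microRNA pathway and 2 of the yolk syncytial layer rose, none of the znf genes passed, and 1 gene each of the germ plasm and Mediator lists fell. With the block and over the list alone, 4 signalling genes and 1 early regulator rose, 3 germ plasm genes fell, 1 elongation gene rose and 2 fell, and 6 znf genes rose and 2 fell. cdk9 had 17.2 ± 4.38 against 7.33 ± 1.21 CPM (adjusted p = 0.406). By camera 5 of 20 lists passed: the early zygotic list (median 0.76, adjusted p = 0.0426), the signalling list (median 0.83, adjusted p = 0.026), the yolk syncytial layer (1.28, adjusted p = 0.0335) and the ribosomal proteins (0.53, adjusted p = 0.024) upward, and the germ plasm list (-0.98, adjusted p = 0.0194) downward. With the block 7 passed, the znf genes (adjusted p = 0.0101) and the histones (adjusted p = 0.0416) in addition. None of the 7 passed with an estimated correlation and no block (adjusted p = 0.989 for each). The early list did not pass without wild type Oblong replicate 1 (adjusted p = 0.426) or mutant Oblong replicate 2 (0.0796) or 3, where its median was 0.49 (adjusted p = 0.117). With the block pcdh8, bmp7a, ell, apoba and slc26a1 rose, hsp90b1, med28 and ddb2 fell, and 6 znf genes rose and 2 fell, znf385c and znf438, and those outside the naming rule were named after their values were seen. The median of all genes was 0.24. DESeq2 gave 324 higher and 267 lower. Without wild type Oblong replicate 1, 2 or 3, 29, 28 or 23 genes were higher, and 81 or 68 lower without its replicate 1 or 3; without mutant Oblong replicate 1, 2 or 3, 39, 50 or 73 were higher and 51, 59 or 64 lower. Without wild type Oblong replicate 1, 0 lists passed, and without mutant Oblong replicate 2, 3.

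At Sphere, 58 genes were higher in the mutant and 104 lower, 43 of them mir430 genes. cmbl had 6.25 ± 3.13 CPM in the mutant against 1 count in wild type, a ratio of 371 (interval 66.3 to 14700). trpc6b, a cation channel gene, had 12.9 ± 7.27 against 0.205 ± 0.169 CPM (SD, n = 3; log2 fold change 6.04, SE 0.96, adjusted p = 0.000449). slc25a23b had 32.8 ± 3.8 against 0.548 ± 0.544 CPM, and purba, dnah3, nyap2b, fgfr1bl and the cadherin gene cdh23 also rose. hsc70, a heat shock cognate gene, had 0 counts in the mutant and 5.76 ± 4.48 CPM in wild type, at least 138-fold lower. rrad had 0.423 ± 0.0683 against 24.8 ± 10.4 CPM (SD, n = 3; adjusted p = 0.00025) and f8 0.591 ± 0.222 against 20.3 ± 11 CPM (adjusted p = 0.00125). cntnap2b, ptprea, pimr201, the hypoxia factor gene epas1b and the clock gene per1b also fell. Of the listed genes, tdrd5 and znf988 fell, the latter with 2 counts in the mutant, a ratio of 152 (interval 41.6 to 1260). Adjusted over the list alone, tdrd5 fell, none of the znf genes passed and 3 yolk syncytial genes rose. The early zygotic list had a median of 0.11 (camera adjusted p = 0.44), which was -0.1, 0.23 or 0.22 without wild type Sphere replicate 1, 2 or 3 and 0.05 or 0.22 without mutant Sphere replicate 1 or 3, and cdk9 had 17.8 ± 6.97 against 12.2 ± 5.87 CPM (adjusted p = 0.917). By camera the ribosomal proteins (median 0.38, adjusted p = 0.00785) and the yolk syncytial layer (median 0.92, adjusted p = 0.0187) passed, and neither did with an estimated correlation (adjusted p = 0.989). DESeq2 gave 144 higher and 175 lower, and total-count scaling 75 and 84, so 47.2% of calls were upward against 35.8%. Without wild type Sphere replicate 2 or mutant replicate 2, 26 or 30 genes were higher; without wild type replicate 3, 215 were lower, and without mutant replicate 1, 2 or 3, 59, 51 or 69. Without wild type Sphere replicate 2 or 3, 6 or 5 lists passed, and without mutant replicate 3, 7.

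The 9 tested genes of the list of textbook miR430 targets were not called at 1024c, Oblong or Sphere. At 256c 1 rose, ackr3b, with 27.2 ± 22.7 against 0.557 ± 0.278 CPM (SD, n = 3; adjusted p = 0.00287). Of the remaining lists, none of the 12 oocyte genes was called at any stage over all genes, and 2 rose at 1024c adjusted over the list alone. In the interferon list irf7 and isg15 rose and stat1a fell at 256c, 3 of 13, and in the heat shock and unfolded protein list atf3 rose and pdia4 fell, 2 of 20, with equal counts adjusted over the list alone. The ribosomal protein pattern had 2 of 90 called at 256c, rps27.2 and rps6ka3a, the latter a kinase gene rather than a ribosomal protein, and 1 at 1024c, rps27.2, with equal counts over the list alone. Of 17 zona pellucida genes 1 rose at 256c, zp2l1, and 1 at 1024c, zp3a.2, where 2 rose adjusted over the list alone. In the germ plasm list tdrd5 was the 1 called gene of 11 at each of the 4 stages, over the list alone too.

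Wild type stages were then compared in order, as the reference course of activation. From 256c to 1024c, 492 genes rose and 1 fell, the clone-named gene CABZ01022569.3, named after its values were seen. With the replicate block 833 rose and 9 fell, in a step where same-numbered libraries deviated alike. Of the 32 early zygotic regulators 14 rose and none fell, and 28 rose adjusted over the list alone, with a median log2 change of 3.97. With the block 22 rose, and by DESeq2 24. The SoxB1 gene sox19a went from 0.775 ± 0.53 to 44.6 ± 29.3 CPM (SD, n = 3; log2 fold change 5.87, SE 1.07, adjusted p = 0.00658). The genes with 0 counts at 256c and the largest rises were drl, at least 44.4-fold higher, znf1137, at least 40-fold, zic2b, at least 29.6-fold, mapk12b, at least 25-fold, and the Wnt agonist gene rspo3, at least 18.8-fold. Without wild type 256c replicate 1 or 2, 0 genes were called, without replicate 3, 109, and without wild type 1024c replicate 3, 23, and these held 0, 0, 6 and 1 of the early regulators.

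From 1024c to Oblong edgeR called 0 genes, with 719 higher and 92 lower at an unadjusted p under 0.05, and DESeq2 also called 0. Adjusted over the list alone 2 enveloping layer genes rose, 4 without wild type Oblong replicate 1 and 0 without wild type 1024c replicate 1 or 2 or Oblong replicate 2 or 3. From Oblong to Sphere edgeR called 0, with 1131 higher and 915 lower at an unadjusted p under 0.05. With the replicate block 0 were called and 3742 had an unadjusted p under 0.05, and same-numbered libraries deviated alike in this step too. Adjusted over the list alone, 6 of 10 yolk syncytial genes, 4 of 23 signalling genes, 2 elongation genes, 1 early regulator and 1 gene of the Mediator and TFIID list rose, and 6 of 17 zona pellucida genes fell. With the block 7 early regulators and 2 cell cycle genes rose, 7 germ plasm genes and 9 zona pellucida genes fell, and 1 gene each of the maternal activator, oocyte and microRNA pathway lists fell. Without wild type Oblong replicate 3 or Sphere replicate 2 or 3, 0 genes of the 6 lists that moved without the block passed, without Oblong replicate 1 only 3 zona pellucida genes did, and without Oblong replicate 2 no signalling gene or early regulator did. Without Sphere replicate 1, 7 germ plasm genes and 11 zona pellucida genes fell and 5 early regulators rose and 1 fell. In that step DESeq2 called 303 higher and 51 lower and total-count scaling 2138 higher and 1 lower. Leaving out wild type Sphere replicate 1 gave 509 higher and 1656 lower, so the direction of that step differed between these choices. edgeR called none of the early zygotic regulators in either step, where from Oblong to Sphere DESeq2 called 4 higher, total-count scaling 9 higher and the fit without wild type Sphere replicate 1 4 higher and 1 lower, and 30 of the 32 were positive from Oblong to Sphere.

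Whether the genotype difference itself changed between consecutive stages was tested directly. No gene was called between 256c and 1024c by edgeR (145 higher and 855 lower at an unadjusted p under 0.05), where DESeq2 called 248. Adjusted over the list alone, the difference was lower at 1024c than at 256c for 11 of the 32 early zygotic regulators (median -3.12), 3 of 13 enveloping layer genes and 1 gene each of the signalling, maternal activator and textbook target lists. Without wild type 256c replicate 1 or mutant 256c replicate 1 it was 4 or 18 early regulators, and without wild type 1024c replicate 3 or mutant 256c replicate 3, 0. No enveloping layer gene passed without wild type 256c replicate 1 or 2, wild type 1024c replicate 3 or mutant 256c replicate 3, and 5 did without mutant 1024c replicate 2. No gene was called between Oblong and Sphere (59 higher and 86 lower at an unadjusted p under 0.05), and DESeq2 called 0. Between 1024c and Oblong 1 gene was called, lsm8, a component of the spliceosomal LSm ring on chromosome 4 between 9536860 and 9539424 (GRCz11). It had 0 counts in the mutant and 1.28 ± 0.416 CPM in wild type at 1024c, and 0.806 ± 0.187 against 0.182 ± 0.0727 CPM at Oblong (SD, n = 3; interaction adjusted p = 0.0179). DESeq2 called 1 gene in that comparison. The lsm8 call was lost without wild type 1024c replicate 3, wild type Oblong replicate 1 or 2, any of the 3 mutant 1024c libraries, or mutant Oblong replicate 2 or 3, each of which gave 0 calls.

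The genes that rose in wild type from 256c to 1024c were followed in the mutant later. At Oblong these 492 genes had a median log2 fold change of 0.59 against 0.24 for all genes (camera adjusted p = 0.000103), and 3 of them were called, all lower in the mutant. The adjusted p = 0.887 with an estimated correlation. With the replicate block the median was 0.92 (adjusted p = 2.15e-07). It was 0.17 without wild type Oblong replicate 1 (adjusted p = 0.927) and 0.92 without replicate 2 (adjusted p = 1.48e-07). At Sphere the median was 0.11 (camera adjusted p = 0.264, and 0.887 with an estimated correlation, which was not run without single libraries) with 4 genes called, all lower, and it was -0.25 without wild type Sphere replicate 1 (adjusted p = 0.000271). It was 0.25 without wild type Sphere replicate 2 (adjusted p = 0.0277), 0.37 without replicate 3 (adjusted p = 0.000147) and 0.25 without mutant Sphere replicate 3 (adjusted p = 0.0266).

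The libraries without IAA were set against the 12 wild type libraries with IAA, as the background of the chemical treatment. Their totals ran from 143490 to 1105928 counts. Nuclear genes held 9.41% of counts at 256c (Wilson 95% interval 9.36 to 9.47), 18.3% at 1024c (18.2 to 18.3), 91.5% at Oblong (91.4 to 91.7) and 81.1% at Sphere (81 to 81.2), with 1 library each. The mir430 genes took 0.528%, 1.26%, 0.695% and 4.12% of nuclear counts there. Wild type libraries with IAA were deeper and held a lower nuclear share, for example 10.5% ± 3.87 at Oblong (SD, n = 3). The calls that follow therefore cannot be assigned to IAA rather than to depth or composition. With IAA, 2 genes were higher and 2 lower of 12267 tested, with 1535 higher and 364 lower at an unadjusted p under 0.05. The higher ones were mitochondrial genes, NC_002333.10 and NC_002333.8, with 29.1 ± 28 and 29.1 ± 32.9 CPM (SD, n = 12) against 2.06 ± 2.7 and 1.44 ± 1.62 CPM (SD, n = 4; adjusted p = 0.0395 for both). The lower ones were CABZ01028323.4 (adjusted p = 0.0218) and AL935280.1 (adjusted p = 0.0395), and all 4 were named after their values were seen. DESeq2 called 617 genes and total-count scaling 8459, and leaving out any of the 4 libraries without IAA left 0 or 1 call.

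At an adjusted p under 0.05 the authors' deposited table holds 1377 genes higher and 597 lower at 256c, 485 and 396 at 1024c, 305 and 251 at Oblong, and 125 and 162 at Sphere. The genes that the authors' deposited table itself classes as changed number 716 higher and 284 lower at 256c, 199 and 170 at 1024c, 92 and 105 at Oblong, and 51 and 74 at Sphere. At 256c those had an adjusted p of at most 0.00999 and a log2 fold change of at least 2 in size in the authors' deposited table. Of the 1394 edgeR calls at 256c that also have an adjusted p in the authors' deposited table, 1378 were under 0.05 there in the same direction and 0 in the opposite one. At 1024c it was 499 of 500, at Oblong 248 of 250 and at Sphere 157 of 162. The log2 fold changes of edgeR and of the authors' deposited table correlated across genes with r = 0.864, 0.86, 0.879 and 0.766 in stage order, over genes, which are not independent replicates.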

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

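The interaction test behind lsm8 was planned. Of the tests on the early zygotic list, thinning, the correlation with the later wild type course, the test of a difference specific to 256c, the test of an error of scale and the test of mutant 256c against wild type 1024c were chosen after the values were seen.

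The gene lsm8 stood out because its genotype difference changed between stages, by 8.82 on the log2 scale between 1024c and Oblong (SE 1.39, edgeR adjusted p = 0.0179). The fitted size depends on 0 counts in the mutant at 1024c and is not a bound. Of 20 splits of the libraries, 2 gave at least 1 call, the real one included, and the highest other split gave 174 calls, so chance cannot be excluded and such a split points to a structure of the samples. For the other 2 differences between stages the real count was 0, reached by 20 of 20 splits, with 0 and 566 calls in the highest other split.

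The rise of the early zygotic regulators at 256c was weighed against technical explanations. With nuclear counts thinned to be equal, 18 of the 27 list members tested were called higher. The list's median log2 fold change was then 3.66 (camera adjusted p = 2.89e-08). Fold changes are already scaled for depth and thinning keeps each gene's expected share, so this median could hardly fall whatever the cause. The thinned calls show only that unequal nuclear depth was not needed for a call in those members. With an estimated correlation the thinned list did not pass (adjusted p = 0.895), nor did the unthinned one (adjusted p = 0.989). After a correction for exonic length and mean expression its median residual was 3.44, which argues against length. An error of library scale would move all genes alike. Under total-count scaling, which is not centred on the genes, all genes had a median of 0.96. The list had a median of 4.85 with a lower quartile of 3.33. An error of scale cannot make a gap between the list and all genes. Any scaling moves both alike, so the gap only restates the list's rise and is no separate test. The 256c difference correlated across genes with the wild type change from 1024c to Sphere, which shares no library with it (r = 0.39, genes are not independent replicates), so mutant 256c libraries that were further along the wild type course may account for part of the rise. A genotype difference specific to 256c stays open as well: the list's difference there exceeded its mean at the other 3 stages by 2.34, with an exact permutation p of 0.17 over 160000 relabellings. Between 256c and 1024c the change in the difference passed over the list alone for 11 of 32 members, and for 0 without wild type 1024c replicate 3 or mutant 256c replicate 3.

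Between mutant 256c and wild type 1024c, 260 genes were higher and 224 lower, 46 of the latter mir430 genes, and of the 32 early regulators none was called, with a median of -0.2. The genes higher in mutant 256c and those that rose in wild type from 256c to 1024c, 972 and 492, shared 373, where independent lists would share 32.5. Both comparisons use the wild type 256c libraries, and part of the excess may come from them. The log2 fold changes had a covariance of 3.57 (r = 0.715) against 0.685 (r = 0.602) in 10 simulations of unchanged groups. The simulated calls shared 0.1 genes on average, but with no gene changed few calls are possible, so this is no baseline for the 373. Genes were drawn independently there, so variation shared across genes is left out of the simulated covariance. The thinned calls bear on depth only, and not on the shared wild type 256c libraries.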

How the results depend on the processing

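Leaving out all libraries numbered 1 and thinning to equal nuclear counts were chosen after the data were seen, the other alternatives before. The cause was not tested for any change below. Each alternative gave values for 103 to 137 of the 137 pairs of a named gene and a comparison. None of these pairs reversed, while 77 of 137 lost their call without at least 1 library. The pairs were chosen among calls, so reversals were unlikely from the start. Asking for a fold of at least 2 as well changed no count of genes. With the replicate block 503 genes were higher at 1024c, 257 higher and 242 lower at Oblong, 112 and 165 at Sphere, 842 were called from 256c to 1024c, 7 lists passed at Oblong and 4 at Sphere, and the early wild type genes had medians of 0.92 at Oblong (adjusted p = 2.15e-07) and 0.47 at Sphere (adjusted p = 0.035). Of the early regulators, 22 then rose from 256c to 1024c and 1 gene each was higher in the mutant at 1024c (isg15) and Oblong (pcdh8), and their median at Sphere was 0.49. The block moved no other total of called genes by over 1.5 times in the comparisons of genotypes, steps and differences between stages. It moved more counts within lists, among them the genes that rose at 256c in the elongation (3 to 5), cell cycle (4 to 8) and yolk syncytial (2 to 4) lists. With an estimated correlation and with fry's test of 1 direction, 0 lists passed at 256c, 0 at 1024c, 0 at Oblong and 0 at Sphere, and with the former the early genes at Oblong, at 0.59, did not pass (adjusted p = 0.887).

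Total-count scaling gave 1901 higher and 185 lower at 256c, 1586 calls from 256c to 1024c, 2139 from Oblong to Sphere (2138 higher), 232 and 0 in the differences between 256c and 1024c and between 1024c and Oblong, and 8459 for IAA. Without a filter there were 1690 higher at 256c, 568 higher at 1024c, 241 higher and 259 lower at Oblong, 149 and 285 at Sphere, 1414, 40 and 1 in the wild type steps, 306 and 0 in those differences, and 375 for IAA. With at least 5 CPM in 3 libraries there were 259 lower at 256c, 46 and 84 at Oblong, 32 and 67 at Sphere, 1036 from 256c to 1024c, and 0 between 1024c and Oblong. With only the stages compared there were 505 and 265 at 256c, 107 and 126 at 1024c, 15 and 42 at Sphere, 880 from 256c to 1024c, and 0 between 1024c and Oblong. With the library without IAA as a 4th wild type library there were 1509 higher at 256c, 529 higher at 1024c, and 0 between 1024c and Oblong. Without mitochondrial and rRNA genes 917 were called from 256c to 1024c. DESeq2 gave 522 and 404 at 1024c, 324 and 267 at Oblong, 144 and 175 at Sphere, 1165 from 256c to 1024c, 354 from Oblong to Sphere (303 higher), 248 between 256c and 1024c, and 617 for IAA.

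Without the libraries numbered 1 there were 219 lower at 256c, 97 and 102 at 1024c, 39 and 68 at Oblong, 1169 from 256c to 1024c, 1028 from Oblong to Sphere (1013 lower), 76 between 256c and 1024c and 0 between 1024c and Oblong. Then 4 lists passed at 1024c and 2 at Oblong, and the early genes had medians of 0.09 at Oblong (adjusted p = 0.741) and -0.19 at Sphere (adjusted p = 1.64e-05), the latter reversed. Thinned, there were 278 lower at 256c, 113 and 99 at 1024c, 16 and 42 at Oblong, 6 and 33 at Sphere and 0 between 1024c and Oblong, 2 lists passed at 1024c, and the early genes at Sphere had a median of 0.21 (adjusted p = 0.00373). Thinning left 160889 nuclear counts per library and 6355 genes tested, so depth limits these counts.

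Leaving out 1 library at a time gave 318 to 1151 higher and 227 to 301 lower at 256c, 88 to 243 and 109 to 162 at 1024c, 23 to 73 and 51 to 99 at Oblong, and 26 to 48 and 51 to 215 at Sphere. The wild type steps gave 0 to 583, 0 and 0 to 2165. Lists past the threshold were 7 to 9 at 256c, 1 to 7 at 1024c, 0 to 7 at Oblong and 2 to 7 at Sphere. The early genes had medians of 0.17 to 0.92 at Oblong and -0.25 to 0.37 at Sphere, reversed at the lower end. The difference between 1024c and Oblong gave 0 to 1 calls and IAA 0 to 1.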

Other observations

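Of the tests in this part, the search for neighbouring genes, the division of the linkage test by chromosome and the tests of single wild type steps without the libraries numbered 1 were chosen after the values were seen.

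The mitochondrial transcripts were led by the rRNA-sized gene NC_002333.4, at positions 2043 to 3725 of the mitochondrial genome. It took 30.7% ± 4.16 of all counts in wild type at 256c, 33.6% ± 4.41 at 1024c, 34.1% ± 1.17 at Oblong and 23.4% ± 11 at Sphere (SD, n = 3). In the mutant it took 31% ± 3.38, 32.1% ± 1.72, 31.6% ± 1.12 and 20.1% ± 5.5. mt-co1, a subunit of cytochrome c oxidase, took 13.6% ± 1.58 in wild type at 256c and 7.61% ± 3.27 at Sphere, and 10.9% ± 0.918 and 5.71% ± 2.21 in the mutant (SD, n = 3). mt-cyb, cytochrome b, took 5.21% ± 0.729 and 2.85% ± 0.807 in wild type at these stages.

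With the mir430 genes left out, a set of 25 genes differed between genotypes in the same direction at all 4 stages, 12 higher and 13 lower. Calls in either direction that were independent between stages would give 0.00485. The comparisons share each gene's estimate of spread, so their calls are not independent and 0.00485 is no baseline for chance. The set held prdx1, gbgt1l4, ap1s3b and purba among the higher genes and tdrd5, sars1, cbr1l, hmgcrb, afmid and cenpo among the lower. A difference in developmental time would need these genes to change over the wild type course. Only 4% of them (1 gene) did so from 256c to Sphere by as much as their genotype difference, which argues against time as the whole difference. The lower genes did fall in wild type over this course, cbr1l from 12.9 ± 6.77 to 1.37 ± 0.704 CPM (SD, n = 3), so a part played by time stays open for them. The higher genes were mixed: prdx1 rose from 0.571 ± 0.509 to 1.33 ± 0.676 CPM and ap1s3b fell from 1.07 ± 0.779 to 0.053 ± 0.0918 CPM. Strain haplotypes carried by the mutant line may contribute and stay open: 2 of the genes had another within 1 Mb, against 1.04 in the mean of 10000 random draws, 4172 of which were as high. Linkage to the mir430 locus on chromosome 4 is argued against for the 22 genes on other chromosomes. It stays open for the 3 genes on chromosome 4 outside the locus (one-sided Fisher's exact p = 0.275), and no biological explanation was tested.

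Few genes were called in the wild type steps after 1024c, and the libraries numbered 1 were weighed as a source. Without them, 1 of the 2 steps gave at least 100 calls. From Oblong to Sphere there were 1028, 15 higher and 1013 lower, so these libraries may account for the low count there. The direction was the reverse of that by DESeq2 with all libraries (303 higher and 51 lower) and stays unsettled. From 1024c to Oblong there were 0, so leaving them out did not raise the count in that step. Only 2 libraries per group remained, so changes could be missed and their part in that step stays open.

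For the genotype comparisons and the wild type steps the 6 libraries allow 10 splits, too few for a share under 0.05. The genotype comparisons gave 1395, 500, 250 and 162 calls in stage order, and the highest other split 0 at each stage, so 1 of 10 splits was as large. Each other split mixed the genotypes within both groups, so real differences widened the spread there and lowered its calls. Its 0 calls are therefore no baseline for chance. The gene lists past the threshold numbered 8, 1, 5 and 2, and the highest other split gave 12, 12, 8 and 9, with 4, 10, 7 and 10 splits as large. The median of the early wild type genes was 0.59 at Oblong against 0.54 in the highest other split (1 split as large), and 0.11 at Sphere against 0.79 (9 as large). The wild type steps gave 493, 0 and 0 calls and the highest other split 0, 0 and 274, with 1, 10 and 10 splits as large. The split with 274 set wild type Oblong replicates 1 and 3 with Sphere replicate 1, which points to a structure of the samples. For the IAA effect, 2 of 60 splits gave at least the 4 real calls, under a share of 0.05, but the highest other split gave 2245. That split set the libraries without IAA at 256c and 1024c with wild type Oblong and Sphere replicate 1, which also points to a structure of the samples. Each other split left at least 1 library without IAA among those with IAA, so real differences widened the spread there. The share therefore decides nothing about chance.

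All 50 mir430 genes tested had higher fitted levels with IAA than without in wild type, with a median log2 fold change of 2.66, and edgeR called 0 of them. They are short copies of one family and not separate observations, and the fit gives 1 value over all stages. At Sphere their share of nuclear counts went the other way, 4.12% without IAA (1 library) against 3.35% ± 1.64 with it (SD, n = 3). At the other stages their share was higher with IAA. On the principal components of all 24 IAA libraries, the first held 52.9% of the variance and the next 12.6%.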
